A study of Homo sapiens with 6 samples.

How the data were processed

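Polysome-associated RNA was sequenced from 3 established human breast cancer cell lines, each kept at 21% oxygen (normoxia) or at 1% oxygen for 8 hours (hypoxia). The lines were SUM1315 (triple negative), SKBR3 (luminal, HER2-positive) and T47D (luminal A). Per the labels' protocols, cells were treated with cycloheximide, which holds ribosomes on their mRNA, lysates with equal protein were separated on sucrose gradients, RNA was isolated from the polysome fractions, and libraries were made with a NEBNext Ultra RNA kit. Each line gave 1 library per oxygen level, so that 6 libraries were compared, 3 per oxygen level. The fractions pooled as polysomes, the read length and the strand setting are not given in the sources used here. RNA from whole lysates of these cells was not analysed here, so a difference in polysome RNA cannot be divided into a change of mRNA amount and a change of ribosome loading.

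The deposited table held 30726 gene symbols and 1 column of values per library. Its unit is not named in a header. It was read as RPKM made by the authors, reads per kilobase of transcript scaled to library size, from the values themselves. In genes with a single GENCODE release 29 transcript, value times transcript length fell on whole multiples of 1 step per library in 60.1% to 63.2% of 2800 to 3047 genes (tolerance 0.02 of a step, where 4% would do so by chance). Whether a step is a read or a read pair is not given in the sources used here. The submitters' processing notes name Trimmomatic, HISAT2, SAMtools and Partek and the builds GRCh38 and hg38, with no versions and no order. The annotation used for counting is not given in the sources used here. Values as small as fractions of a step occurred, as estimates that divide reads among overlapping transcripts give.

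By the size of the step, 1 RPKM on a transcript of 1 kb stands for 22.0 (SUM1315 hypoxia), 21.7 (SUM1315 normoxia), 27.7 (SKBR3 hypoxia), 33.4 (SKBR3 normoxia), 22.2 (T47D hypoxia) and 24.1 (T47D normoxia) reads or read pairs. A count of 3 stands for 0.0897 to 0.138 RPKM there. This covers counting error only.

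Values were taken as deposited. As RPKM is scaled to library size, a gene that rose or fell did so as a share of the polysome RNA sequenced. A change in the total mRNA on polysomes cannot be seen in such values. Genes at 1 RPKM or more in at least 3 of the 6 libraries were kept, which left 10253 genes. A gene that reached 1 RPKM in only 1 line was thus not tested. Hypoxia was compared with normoxia on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model with cell line as a block, mean-variance trend, no robust option, two-sided, Benjamini-Hochberg adjusted p under 0.05). A fold change on this scale understates the change of genes with low RPKM. Because the values turned out to be RPKM, the version of the test fixed for normalized values was used. The lines are the labels' own pairing: the deviations of a line's 2 libraries from their oxygen group means correlated across genes at 0.97 in SUM1315 and 0.94 in both SKBR3 and T47D. Nothing in the labels replicates a line, so the lines are the only replication. The p-values and SE use a spread between these 3 pairs of libraries that limma moderates toward that of genes of like expression. Prior degrees of freedom were 8.02 against 2 residual ones. An SE therefore reflects other genes more than the gene's own 3 pairs. A log2 ratio within a line compares 1 library with 1 library and was not tested.

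Before the data were examined, 27 gene lists, a panel of 26 genes and the rule for naming genes were fixed. Each list was compared with all other tested genes with limma's camera (inter-gene correlation preset at 0.01, Benjamini-Hochberg over the 27 lists), beside camera with a correlation estimated from the residuals and beside fry, which asks whether a list's genes move one way on balance. Camera with an estimated correlation tests on the 2 residual degrees of freedom, which leaves it little power over 27 lists. A list that no longer passes there has therefore not been shown to fail through gene correlation. RNA polymerase I and G1/S genes had estimated correlations of -0.066 and -0.018, below the preset 0.01, and still no longer passed. Within a line, a list's median log2 ratio was set beside 10000 random lists of the same size drawn from the same 20 bins of mean expression, giving a percentile that describes these libraries only. Genes were named by 4 parts of a rule: the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05 that moved the same way in all 3 lines; the panel, whatever its values; the 2 largest rises and 2 largest falls of each list described; and within each line the 5 largest and 5 smallest log2 ratios among the genes in the upper part of that line's RPKM, split at the median. Other members of a list that passed the test are named as examples from its results, chosen after their values were seen.

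The limma fit was tested on simulated data with 200 changed genes among the 10253 and the residual spread of these libraries. It recovered 60% of genes changed by 1 on the log2 scale and 95% of those changed by 2. Of its calls, 0.641% were unchanged genes. The noise was drawn independently for each gene, and each change was the same in all 3 lines. Residuals of the real libraries correlated within some lists (estimated at 0.33 in ribosomal proteins). The share of false calls among real calls was therefore not measured. Coordinates, coding lengths, transcript lengths and GC content came from GENCODE release 29 on GRCh38, taking for each gene the transcript with the longest coding sequence. That annotation matched 28604 of the 30726 symbols (93.1%). Gene properties and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

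Alternatives chosen in advance were median-of-ratios scaling, quantile normalization, no filter on low values, a minimum of 5 RPKM, limma without the mean-variance trend, pseudocounts of 0.1 and 5, no block for cell line, an adjusted p under 0.10, and each line left out in turn. A fit after removing trends with expression level, transcript length and GC content within each line (natural splines with 4 degrees of freedom each) was added after seeing the data. All columns of the table belonged to the 6 libraries.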

Results

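The data were RPKM values of polysome-associated RNA from SUM1315, SKBR3 and T47D breast cancer cells at 1% oxygen for 8 hours and at 21% oxygen, with 1 library per line and oxygen level. The labels state the purpose as finding how hypoxia affects the translation of transcripts, and the series title names ribosome biogenesis and HIF1A. Between 9675 and 10842 genes per library stood at 1 RPKM or more. At the depth implied by the values, 1 RPKM stood for 21.7 to 33.4 reads or read pairs per kilobase of transcript. Libraries of the same line correlated at 0.972 to 0.980 across genes, and libraries of different lines at 0.678 to 0.846.

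Under hypoxia, most polysome-associated mRNAs of HIF targets and of glycolysis rose (30 of 37 and 18 of 22), and 31 of 79 ribosomal protein mRNAs and 20 of 107 ribosome biogenesis factor mRNAs fell. Of 10253 genes tested, 422 were higher and 232 were lower at adjusted p under 0.05. Each of these 654 had a log2 ratio of the same sign, however small, in all 3 lines. Rises were larger than falls: 99 genes rose by at least 1 on the log2 scale and 7 fell by as much. The largest rise was that of DDIT4, an inhibitor of mTORC1 signalling, at a log2 fold change of 3.60 ± 0.17 (SE, n = 3 lines, adjusted p = 1.05e-05). Its RPKM went from 63.3 to 997 in SUM1315, from 76.3 to 853 in SKBR3 and from 14.3 to 159 in T47D. The DDIT4 gene lies on chromosome 10 at 72273920 to 72276036 (GRCh38, plus strand). After it came ANGPTL4 (3.21 ± 0.24), a secreted inhibitor of lipoprotein lipase, the mitophagy receptors BNIP3 (2.80 ± 0.24) and BNIP3L (2.42 ± 0.18), ANKRD37 (2.78 ± 0.20), the glycolytic regulator PFKFB4 (2.75 ± 0.16), the lipid droplet protein HILPDA (2.51 ± 0.19), the noncoding host of the hypoxia microRNA miR-210, MIR210HG (2.50 ± 0.13), the glucose transporter SLC2A1 (2.46 ± 0.14) and the lactate transporter SLC16A3 (2.38 ± 0.30). The largest falls were in IDH3A (-1.08 ± 0.16), a subunit of the mitochondrial isocitrate dehydrogenase, the ribosomal protein RPL26 (-1.07 ± 0.20), the splicing factor PRPF4 (-1.06 ± 0.16), AUNIP (-1.04 ± 0.16), the PRMT5 partner WDR77 (-1.03 ± 0.15), the exonuclease AEN (-1.03 ± 0.13), the dolichol kinase DOLK (-1.02 ± 0.16), HNRNPAB (-0.99 ± 0.18), the nucleolar hydroxylase RIOX1 (-0.99 ± 0.15) and the small-subunit assembly factor LTV1 (-0.98 ± 0.14). All 20 of these genes stayed past the threshold with any line left out. The counts were 179 higher and 53 lower without T47D, and 171 and 72 with a pseudocount of 5. With limma no gene was called without the block for cell line (68 at an unadjusted p under 0.05, against 2692 with it) or without the expression filter (2715 of 27552).

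**Figure D1:**
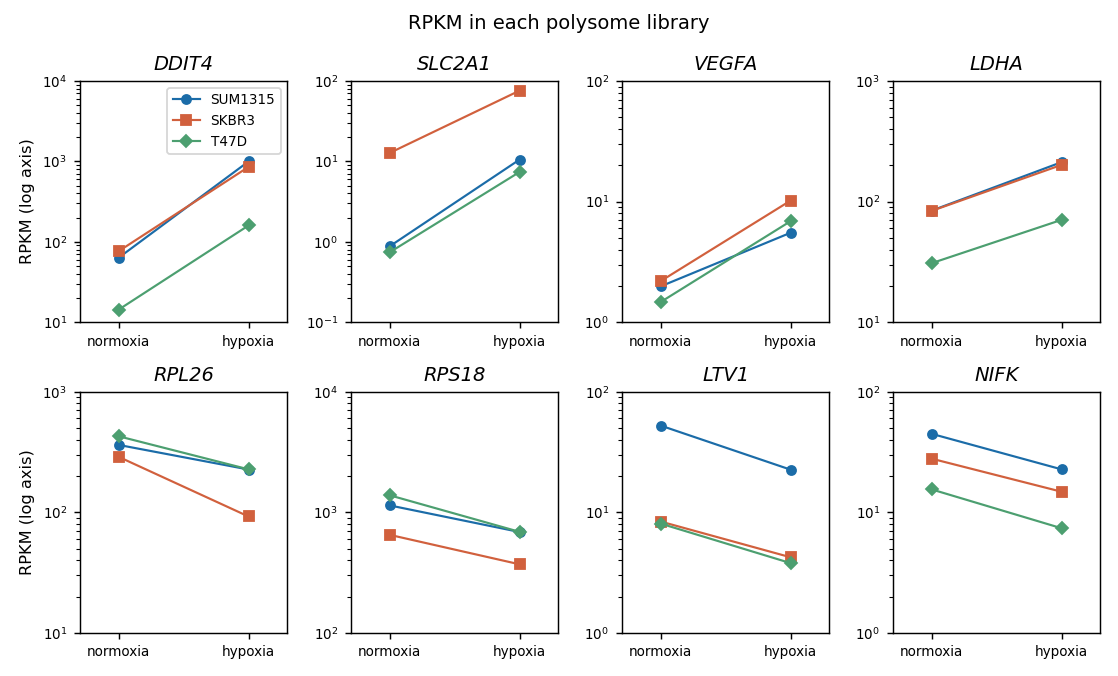
RPKM on a log axis (y) at normoxia and hypoxia (x) for 4 genes that rose and 4 that fell, with 1 marker per library and a line joining the 2 libraries of each cell line. Each of the 8 genes moved the same way in SUM1315, SKBR3 and T47D, as DDIT4 did from 14.3 to 159 RPKM in T47D.

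Of the 37 HIF targets tested, 30 rose, none fell and 7 did not pass (35 rose and 1 fell when adjusted over the list alone). The list median was 1.54 on the log2 scale, with medians of 1.57 in SUM1315, 1.37 in SKBR3 and 1.58 in T47D. Besides the genes above, the angiogenic factor VEGFA rose by 1.54 ± 0.16 (adjusted p = 0.000884), from a mean of 1.88 ± 0.37 to 7.52 ± 2.40 RPKM (SD, n = 3). ADM (2.32 ± 0.32), NDRG1 (1.70 ± 0.26) and the pyruvate dehydrogenase kinase PDK1 (1.37 ± 0.13) also rose. Among those that did not pass were LOXL2 (0.76), STC2 (0.71), PLOD2 (0.65), LOX (0.56), WSB1 (0.24) and CA12, which had a log2 fold change of -0.52 ± 0.21 (adjusted p = 0.16). CA9 and EGLN3 were below the expression filter: in SKBR3 their values were 0.316 and 1.80 RPKM at normoxia and 9.40 and 14.1 RPKM at hypoxia. In the other 4 libraries both were under 1 RPKM. In T47D CA9 went from 0 to 0.946 RPKM and EGLN3 from 0.236 to 0.868 RPKM. In SUM1315 CA9 went from 0 to 0.0283 RPKM and EGLN3 from 0.0188 to 0.105 RPKM. Of 22 genes of glycolysis and glucose transport, 18 rose and none fell (20 rose when adjusted over the list alone), with a median of 1.24. HK2, a hexokinase, rose by 2.25 ± 0.15 and LDHA, which makes lactate, by 1.25 ± 0.15, and the 4 that did not pass were ENO2 (1.31 ± 0.36), TPI1 (0.46), PFKL (0.30) and PGAM1 (0.28). The camera adjusted p was 8.48e-35 for HIF targets and 4.68e-21 for glycolysis. It was 0.25 for both with an estimated correlation, a version that tests on 2 degrees of freedom. The adjusted p of fry was 0.020 for both. The mRNAs of the HIF subunits themselves did not pass: HIF1A had 0.26 ± 0.15 (adjusted p = 0.31), EPAS1 0.47 ± 0.20 (adjusted p = 0.17) and ARNT 0.22 ± 0.13 (adjusted p = 0.30).

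**Figure D2:**
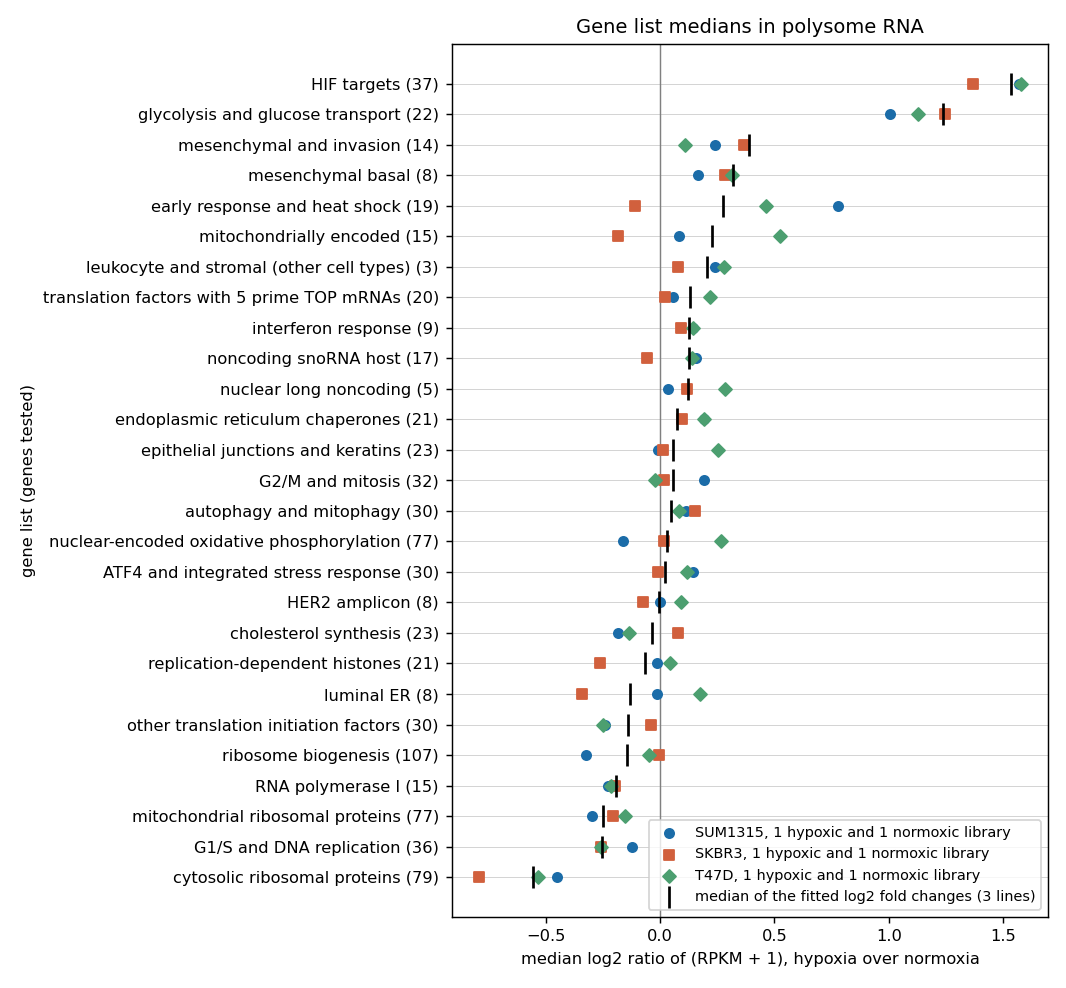
Median log2 ratio of (RPKM + 1), hypoxia over normoxia (x), of each of the 27 fixed gene lists (y, with the number of genes tested), per cell line (markers, 1 library against 1) and as the median of the fitted fold changes (black bars). HIF targets lie at 1.37 to 1.58 and cytosolic ribosomal proteins at -0.79 to -0.45 in the 3 lines.

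Cytosolic ribosomal protein mRNAs were lower on polysomes under hypoxia in every line. Of 79 tested, 31 fell, none rose and 48 did not pass (61 fell when adjusted over the list alone), and 75 of the 79 fold changes were below 0. The list median was -0.56 on the log2 scale, at -0.45 in SUM1315, -0.79 in SKBR3 and -0.53 in T47D, each at percentile 0 of random lists of the same expression. RPL26 went from 362 to 226 RPKM in SUM1315, from 288 to 92.3 in SKBR3 and from 427 to 227 in T47D. RPL27A (-0.90 ± 0.16), RPL21 (-0.89 ± 0.15) and RPS18 (-0.85 ± 0.15) also fell. RPS6, the ribosomal protein phosphorylated by S6 kinases, had -0.59 ± 0.17 (adjusted p = 0.066). RPL3 (0.06 ± 0.15), RPL41 (0.14 ± 0.15) and RPS28 (0.16 ± 0.15) did not pass. The camera adjusted p was 2.05e-23 and was 0.44 with an estimated correlation, and the adjusted p of fry was 0.094. Ribosomal protein genes share sequence with processed pseudogenes, so their values are uncertain where reads could be divided: 296 named pseudogenes in the table held 0.953% to 1.34% of the RPKM sum of ribosomal protein genes and pseudogenes together.

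Ribosome biogenesis factors did not move as 1 group. Of 107 tested, 20 fell, 2 rose and 85 did not pass (28 fell and 4 rose when adjusted over the list alone), with 63 fold changes below 0 and 44 above. The falls were led by LTV1 (-0.98 ± 0.14), NIFK (-0.93 ± 0.14), a partner of the proliferation marker Ki-67, and LYAR (-0.92 ± 0.14), followed by NOP16 (-0.88 ± 0.15) and PAK1IP1 (-0.88 ± 0.15). Their adjusted p values ran from 0.0069 to 0.013. The 2 rises were nucleolin, NCL (0.69 ± 0.15, adjusted p = 0.027), and the RNA acetyltransferase NAT10 (0.68 ± 0.13, adjusted p = 0.022). The NCL call was lost without SKBR3 (adjusted p = 0.059) or T47D (adjusted p = 0.071), and the NAT10 call without T47D (adjusted p = 0.12). The rRNA methyltransferase fibrillarin, FBL, had 0.02 ± 0.15 (adjusted p = 0.95) and NPM1 had -0.09 ± 0.15 (adjusted p = 0.73). The list median was -0.14, at -0.33 in SUM1315, -0.01 in SKBR3 and -0.05 in T47D. The camera adjusted p was 0.0039, and it was 0.70 with an estimated correlation; the adjusted p of fry was 0.29. With each line left out in turn the camera adjusted p (preset correlation) ran from 3.05e-06 (without SKBR3) to 0.34 (without SUM1315).

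Of 15 subunits and factors of RNA polymerase I, which transcribes the large rRNA precursor, 2 fell and none rose (3 fell when adjusted over the list alone). They were POLR1G (-0.71 ± 0.14, adjusted p = 0.021) and POLR1C (-0.53 ± 0.13, adjusted p = 0.038). The POLR1C call was lost without SUM1315 (adjusted p = 0.060), SKBR3 (adjusted p = 0.054) or T47D (adjusted p = 0.18). The transcription factor UBTF had -0.24 ± 0.14 (adjusted p = 0.28), the subunit POLR1B -0.28 ± 0.12 (adjusted p = 0.17), TTF1 0.28 ± 0.12 (adjusted p = 0.19) and TAF1D 0.13 ± 0.14 (adjusted p = 0.58). The list median was -0.19. Its camera adjusted p was 0.044, and it was 0.44 with an estimated correlation; the adjusted p of fry was 0.020. With a line left out the camera adjusted p (preset correlation) was 0.043 (without SKBR3), 0.078 (without T47D) and 0.085 (without SUM1315).

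**Figure D3:**
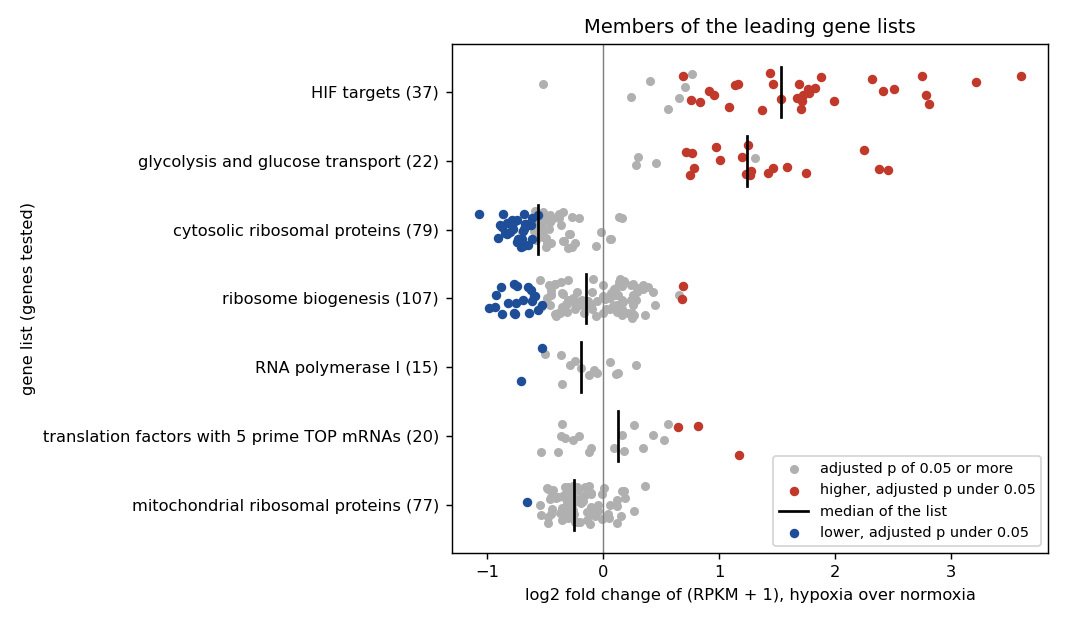
Fitted log2 fold change of (RPKM + 1), hypoxia over normoxia (x), of each tested member of 7 gene lists (y; vertical scatter within a list only separates points), with genes past adjusted p of 0.05 in red (higher) or blue (lower), others in grey and the list median as a black bar. In the list of cytosolic ribosomal proteins 31 of 79 members are blue and in that of HIF targets 30 of 37 are red.

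Other mRNAs of the translation machinery went both ways. Of 20 translation factors and related genes whose mRNAs carry a 5 prime TOP motif, as ribosomal protein mRNAs do, 3 rose and none fell (4 rose and 1 fell when adjusted over the list alone). These were the elongation factor EEF2 (1.17 ± 0.19, adjusted p = 0.010), EIF4B (0.81 ± 0.15, adjusted p = 0.018) and EIF3D (0.64 ± 0.16, adjusted p = 0.039). EEF2 went from 284 to 722 RPKM in SUM1315, from 211 to 326 in SKBR3 and from 103 to 300.0 in T47D. The EIF4B call was lost without T47D (adjusted p = 0.058). At the low end TPT1 had -0.53 ± 0.17 (adjusted p = 0.085) and EIF3K -0.38 ± 0.15 (adjusted p = 0.15). The list did not pass (camera adjusted p = 0.42). Of 30 other initiation factors, EIF3A (1.32 ± 0.16, adjusted p = 0.0021) and EIF3C (1.03 ± 0.16, adjusted p = 0.0079), whose near-identical copy EIF3CL leaves its reads uncertain, rose and none fell (2 rose and 3 fell when adjusted over the list alone), and EIF3J (-0.56 ± 0.15, adjusted p = 0.060) and EIF5 (-0.54 ± 0.16, adjusted p = 0.071) were lowest. That list did not pass either (camera adjusted p = 0.26).

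Mitochondrial ribosomal protein mRNAs lay slightly lower, with 64 of 77 fold changes below 0 and a median of -0.25, but only MRPL15 passed (-0.66 ± 0.17, adjusted p = 0.048; none passed when adjusted over the list alone). Its call was lost without SUM1315 (adjusted p = 0.11) or T47D (adjusted p = 0.19). MRPL3 was next, at -0.55 ± 0.15 (adjusted p = 0.060), and MRPL33 (0.36 ± 0.15, adjusted p = 0.16) and DAP3 (0.26 ± 0.15, adjusted p = 0.28) were highest. The camera adjusted p of the list was 1.30e-05, and it was 0.44 with an estimated correlation. None of the 77 nuclear genes of oxidative phosphorylation and none of the 15 mitochondrially encoded genes passed with limma, over all genes or when adjusted over the list alone (7 and 3 had an unadjusted p under 0.05). Their medians were 0.03 (camera adjusted p = 0.61) and 0.23 (camera adjusted p = 0.26).

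In the list of early response and heat shock genes, 6 of 19 rose and 1 fell, the same numbers as when adjusted over the list alone. DUSP1, a MAP kinase phosphatase, rose by 1.34 ± 0.22 (adjusted p = 0.011), and JUN, HSPD1, JUNB, MYC and KLF6 rose by 0.66 to 1.13. The co-chaperone DNAJB1 fell by 0.72 (SE 0.15, adjusted p = 0.026), with that call lost without SUM1315 (adjusted p = 0.052) or SKBR3 (adjusted p = 0.059). MYC, a transcription factor that drives ribosome production, had 0.89 ± 0.19 (adjusted p = 0.027) and was not past the threshold without SUM1315 (adjusted p = 0.071) or T47D (adjusted p = 0.071). EGR1 had 1.19 ± 0.47 (adjusted p = 0.15), with a log2 ratio of 3.24 in SUM1315 and 0.17 and 0.16 in SKBR3 and T47D. The list's camera adjusted p was 0.0036, and 0.67 with an estimated correlation.

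Of 36 genes of G1/S and DNA replication, 5 fell and 2 rose (8 fell and 4 rose when adjusted over the list alone). The clamp protein PCNA (-0.90 ± 0.19, adjusted p = 0.028), cyclin E1, CCNE1 (-0.83 ± 0.20, adjusted p = 0.040), RFC3, CDC45 and GINS3 fell, and RRM1 (0.71 ± 0.13, adjusted p = 0.018) and CDT1 (0.55 ± 0.14, adjusted p = 0.047) rose. The PCNA and CCNE1 calls were lost without SKBR3 (adjusted p = 0.085 and 0.082), and those of PCNA, RRM1 and CDT1 without T47D (adjusted p = 0.076, 0.057 and 0.16). CDT1 was not past the threshold without SUM1315 (adjusted p = 0.080) or SKBR3 (adjusted p = 0.088) either. The camera adjusted p of the list was 0.028, and 0.44 with an estimated correlation. In the G2/M list only TOP2A passed, upward, among 32 genes (0.55 ± 0.14, adjusted p = 0.044; 4 rose when adjusted over the list alone), and its call was lost without SUM1315 (adjusted p = 0.098), SKBR3 (adjusted p = 0.082) or T47D (adjusted p = 0.12). That list did not pass (camera adjusted p = 0.45).

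Of 32 mesenchymal and invasion genes, 14 were above the filter. Of these ANGPTL4 alone passed, and it is also a HIF target (2 passed when adjusted over the list alone). The list median was 0.39 (camera adjusted p = 0.0096, and 0.44 with an estimated correlation). Of 14 mesenchymal basal markers, 8 were above the filter. None of these passed with limma, over all genes or when adjusted over the list alone (3 had an unadjusted p under 0.05). Their median was 0.32 (camera adjusted p = 0.044, and 0.44 with an estimated correlation; adjusted p of fry 0.020). That list's camera call was lost without SUM1315 (adjusted p = 0.11) or SKBR3 (adjusted p = 0.094). The medians and camera tests of both lists leave out genes that reached 1 RPKM in SUM1315 only. Among those in both lists, AXL went from 121 to 113 RPKM and CD44 from 45.9 to 62.6 RPKM in SUM1315. Vimentin, VIM, had 0.54 ± 0.26 (adjusted p = 0.21): it went from 407 to 1161 RPKM in SUM1315 and stayed between 4.96 and 9.17 RPKM in the other 2 lines. TGFB1 had 1.04 ± 0.52 (adjusted p = 0.23), with a log2 ratio of 3.26 in SKBR3, -0.18 in SUM1315 and 0.03 in T47D. SNAI2 was below the filter, at 3.96 RPKM in hypoxic and 4.20 RPKM in normoxic SUM1315.

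The remaining lists did not pass with camera. In the ATF4 and integrated stress response list 3 of 30 rose and 1 fell (camera adjusted p = 0.28; 8 rose and 3 fell when adjusted over the list alone). The tRNA synthetase EPRS1 rose by 0.89 ± 0.13 (adjusted p = 0.0081) and the transcription factor ATF5 had -0.81 ± 0.14 (adjusted p = 0.015), while ATF4 itself had -0.08 ± 0.25 (adjusted p = 0.85). Of 21 endoplasmic reticulum chaperones EDEM1 rose (0.54 ± 0.14, adjusted p = 0.049) and none fell (5 rose and 1 fell when adjusted over the list alone). In the list of 23 cholesterol synthesis genes MVK fell by 0.73 (SE 0.15, adjusted p = 0.024), a call lost without T47D (adjusted p = 0.13), and it was the 1 gene that fell when adjusted over the list alone. Of 23 epithelial junction and keratin genes DSP (1.27 ± 0.30), JUP (0.81 ± 0.18) and MUC1 (0.77 ± 0.14) rose. The DSP and JUP calls were lost without SKBR3 (adjusted p = 0.12 and 0.073) or T47D (adjusted p = 0.13 and 0.14). Both genes were near 0 in SUM1315, where DSP went from 0.0229 to 0.0407 RPKM and JUP from 0.112 to 0.331 RPKM. Of 30 autophagy and mitophagy genes only the HIF targets BNIP3 and BNIP3L rose. Adjusted over the list alone, 3 epithelial and 2 autophagy genes rose. The camera adjusted p of these 4 lists was 0.30, 0.64, 0.30 and 0.28, and the adjusted p of fry was 0.021 for autophagy and mitophagy and 0.27 to 0.84 for the other 3. Of 21 replication-dependent histones H4C12 alone rose (0.56 ± 0.14, adjusted p = 0.046; none when adjusted over the list alone; camera adjusted p = 0.61), with the call lost without SUM1315 (adjusted p = 0.12), SKBR3 (adjusted p = 0.096) or T47D (adjusted p = 0.070). With limma no member passed among 9 interferon response genes (camera adjusted p = 0.39), 17 noncoding snoRNA host genes (0.23), 5 nuclear long noncoding RNAs (0.45), 8 HER2 amplicon genes (0.95), 8 luminal ER genes (0.73) and 3 leukocyte and stromal genes (0.45). In that order 1, 5, 1, 2, 4 and 0 of them had an unadjusted p under 0.05, and when adjusted over the list alone 4 snoRNA hosts rose and 1 gene rose and 1 fell in each of the HER2 amplicon and luminal ER lists. The camera direction was down for those last lists and their medians were -0.0053 and -0.13, while their means were above 0 (0.0048 and 0.0057). Histone genes of 1 cluster share sequence, which leaves their values uncertain.

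Within each line, without a test, 149 genes were at least 2-fold higher and 8 at least 2-fold lower in SUM1315, 188 and 64 in SKBR3, and 206 and 100 in T47D, of the same 10253. The genes at least 2-fold higher overlapped: 39 were shared by all 3 lines, where independent lists would share 0.0549. None of the genes at least 2-fold lower was shared by all 3. Log2 ratios correlated across genes at 0.60 (Pearson) between SUM1315 and T47D, 0.49 between SKBR3 and T47D and 0.45 between SUM1315 and SKBR3, where genes are not independent replicates. With a pseudocount of 0.1 the counts were 307 and 44 in SUM1315, 352 and 151 in SKBR3 and 453 and 186 in T47D, and with 5 they were 61 and 2, 85 and 29, and 83 and 25. DDIT4 was among the 5 largest log2 ratios of every line. In SUM1315 the others were SLC16A3 (3.54), EGR1 (3.24), BNIP3 (3.14) and PFKFB4 (3.05), and the smallest were COA3 (-1.35), LTV1 (-1.18), PRPF4 (-1.08), LYAR (-1.06) and PAK1IP1 (-1.06). In SKBR3 the others were ANGPTL4 (3.95), ADM (3.57), ANKRD37 (3.29) and TGFB1 (3.26), and the smallest were CHAC2 (-1.70), RPL26 (-1.63), CCNE1 (-1.50), RPS15A (-1.43) and RPS20 (-1.42). In T47D the others were BNIP3 (3.31), ANGPTL4 (3.24), SPAG4 (2.82) and PFKFB4 (2.80), and the smallest were TARDBP (-1.52), PSMD11 (-1.49), IDH3A (-1.45), ELL3 (-1.41) and SRSF1 (-1.41). RPS20 had log2 ratios of 0.18 in SUM1315 and 0.20 in T47D, against -1.42 in SKBR3.

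The genes of the HER2 and estrogen receptors were highest in SKBR3 and T47D, which are known as HER2-positive and luminal A lines. Markers of the mesenchymal basal list were highest in SUM1315, except LGALS1 and S100A4. ERBB2, the HER2 receptor gene, stood at 743 and 615 RPKM in hypoxic and normoxic SKBR3 and at 5.34 to 8.76 RPKM in the other 4 libraries. ESR1, the estrogen receptor gene, stood at 4.54 and 5.18 RPKM in T47D and below 1 RPKM elsewhere. VIM and CAV1 were high in SUM1315 (407 to 1161 and 388 to 420.5 RPKM) and below 10 RPKM in the other lines. AXL stood at 113 to 121 RPKM and CD44 at 45.9 to 62.6 RPKM in SUM1315, and both were below 1 RPKM in the other lines. The galectin gene LGALS1 stood at 1407 to 1420.1 RPKM in SUM1315 and 1560 to 1929 RPKM in T47D. For S100A4 the values were 204 to 244 RPKM in SUM1315 and 1250.5 to 1949 RPKM in SKBR3. SPARC, though highest in SUM1315, stood at only 0.108 and 0.129 RPKM there. Of the 2 receptor genes, ERBB2 was tested between oxygen levels and did not pass (0.14 ± 0.15, adjusted p = 0.58), and ESR1 was below the filter.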

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

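The tests of the ribosomal protein pattern and the count over other splits of the libraries were chosen after the results were seen, and the test of the oxidative phosphorylation pattern was set down before its value was known. The splits are too few for a share under 0.05: the real split called 654 genes, and 1 of 10 splits called as many, the real one included. The highest other split called 0, as did each of the 3 others that also part all 3 pairs. In every other split a response shared by the lines enters the residual spread. The 0 calls there therefore set no chance level for the 654.

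Some gene lists had medians of opposite sign in a pair of lines, with a difference between the lines beyond that of at least 99% of random lists of the same expression. Each rests on 1 library against 1, and the difference was not tested across replicates. The medians below 0 lay within the range of random lists of their line, at percentile 13.6 (oxidative phosphorylation, SUM1315), 31.1 (mitochondrially encoded, SKBR3) and 50.3 (early response, SKBR3). Those above 0 did not: oxidative phosphorylation lay at percentile 99.99 and mitochondrially encoded genes at 99.965 in T47D. Early response genes lay at percentile 100 in SUM1315 and 99.96 in T47D. So the rises lay outside the range of random lists, and the falls did not. The differences lay outside it because the lists were picked by them. Residuals correlated within these lists (estimated at 0.34 in oxidative phosphorylation, 0.34 in mitochondrially encoded and 0.42 in early response genes). Random lists do not allow for this, so these percentiles may be too extreme. The median log2 ratio of nuclear-encoded oxidative phosphorylation genes was -0.16 in SUM1315 and 0.27 in T47D, a difference of -0.43. That of mitochondrially encoded genes was -0.18 in SKBR3 and 0.52 in T47D, a difference of -0.71. That of early response and heat shock genes was 0.78 in SUM1315, -0.11 in SKBR3 and 0.46 in T47D, so that SUM1315 stood above SKBR3 by 0.89 and SKBR3 differed from T47D by -0.57.

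Ribosomal protein mRNAs were lower in all 3 lines, with a median log2 fold change of -0.56. The tables argue against a trend with expression level, transcript length or GC content as the whole cause, since the median was -0.52 (SD over lines 0.18) after that trend was removed, and against reads moved to processed pseudogenes, since sums of parent and named pseudogenes had a median of -0.55 (SD 0.17). They also argue against a loss of short mRNAs from the polysome fraction, since 103 other genes of like coding length and expression lay above the list by 0.58 (SD 0.23), and against abundant genes as a class taking a smaller share, a further test in which 1973 other genes of the top 1 of 5 expression bins lay above the list by 0.53 (SD 0.16). A candidate explanation is lower loading of mRNAs with a 5 prime TOP motif, but 20 translation factor genes of that class had a median of 0.13 and EEF2 rose, so a fall shared by the whole class is not what these values show. A lower amount of the mRNAs in the cells stays open, since RNA from whole lysates was not analysed here.

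The T47D median of oxidative phosphorylation genes (0.27) may in part reflect a trend of T47D ratios with expression level, transcript length or GC content. After the trend was removed it was 0.16, which lies between the bounds set for and against that explanation, so the trend cannot be told apart from a difference of the line. A biological difference between these lines was not tested, since each has 1 library per oxygen level.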

How the results depend on the processing

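The removal of trends with expression, length and GC content was chosen after the data were seen, the other alternatives before. No gene called as reported was called in the opposite direction under any alternative, and no scaling moved the median fold of all genes by 0.1. These scalings also bring the libraries to a common level, so they could not show a change in total polysome mRNA. The log2 fold changes of named genes kept direction and side of the threshold in 1487 gene-by-alternative pairs, passed anew in 76 and no longer passed in 199. Tests of lists kept both in 339 pairs, passed anew in 4 and no longer passed in 34. Medians within lines moved by less than their spread over lines in 464 pairs and by more in 98. The ribosomal protein median was -0.56 under median-of-ratios scaling and -0.53 under quantile normalization. Genes higher and lower numbered 171 and 72 with a pseudocount of 5 and 844 and 616 at adjusted p under 0.10. At a minimum of 5 RPKM they numbered 293 and 299, so the excess of higher over lower genes was not present among these 5525 genes. With limma they numbered 0 and 0 with no filter (2715 at an unadjusted p under 0.05), where prior degrees of freedom fell from 8.02 to 1.2, and 0 and 0 with no replicate block (68 at an unadjusted p under 0.05), where the differences between lines enter the residual SD (median 0.60 against 0.15). Leaving out 1 line gave 179 (without T47D) to 552 (without SUM1315) higher and 53 (without T47D) to 271 (without SUM1315) lower. With an estimated correlation, and so on 2 degrees of freedom, the camera adjusted p was 0.25 for HIF targets, 0.44 for ribosomal proteins, 0.70 for ribosome biogenesis and 0.44 for RNA polymerase I. With fry the adjusted p was 0.020 for HIF targets, 0.094 for ribosomal proteins, 0.29 for ribosome biogenesis and 0.020 for RNA polymerase I. RNA polymerase I had a camera adjusted p (preset correlation) of 0.094 at a minimum of 5 RPKM and 0.053 with a pseudocount of 5. That p was 0.17 with no replicate block and 0.19 after trend removal, where 80% of the list's genes had the properties needed. It was 0.043 to 0.085 with a line left out. Ribosome biogenesis had a camera adjusted p of 3.05e-06 (without SKBR3) to 0.34 (without SUM1315). Genes at least 2-fold higher and lower numbered 307 and 44 (SUM1315), 352 and 151 (SKBR3) and 453 and 186 (T47D) with a pseudocount of 0.1, and 61 and 2, 85 and 29, and 83 and 25 with 5, as a larger pseudocount shrinks ratios of low values. At a minimum of 5 RPKM, which tests fewer genes, 92 were higher in SUM1315, and the medians of endoplasmic reticulum chaperones in SKBR3 (-0.021) and of epithelial genes in T47D (-0.085) changed sign. Except where a reason is given, the cause was not tested. Depth limits values near 0.0897 to 0.138 RPKM on 1 kb, which stand for 3 reads or pairs.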

Other observations

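The lists and the comparison with random lists in this part were chosen after the data were seen, and the test after trend removal was set down before its value was known. Of 44 genes of the 2-oxoglutarate dioxygenase family, oxygen-using enzymes, 6 rose and 1 fell: the collagen prolyl hydroxylases P4HA1 (1.82) and P4HA2 (0.91), the HIF prolyl hydroxylase EGLN1 (1.16), the histone demethylases KDM3A (1.09) and KDM4B (0.83) and PLOD1 (0.95) rose, and RIOX1 (-0.99) fell. All 6 that rose are also members of the list of HIF targets and counted there. Of 44 SR proteins and hnRNPs, 6 rose, among them KHDRBS1 (1.13) and NONO (1.05), and HNRNPAB (-0.99) fell. Of 24 HSP90 and TRiC chaperone genes, HSP90AB1 (1.44) and CCT8 (0.86) rose and AHSA1 (-0.87), HSPA14 (-0.86) and CHORDC1 (-0.70) fell. Of 25 genes of the tricarboxylic acid cycle, IDH3A (-1.08) and PDHX (-0.67) fell and none rose. None of these 4 lists passed as a whole (camera adjusted p = 0.33, 0.52, 0.42 and 0.42 over 5 lists). In a list of 34 ubiquitin and proteasome genes, PSMD11 (-0.84) and PSMD12 (-0.62) fell; the list median was -0.25 (camera adjusted p = 0.0027, and 0.82 with an estimated correlation), and the PSMD11 call was lost without T47D (adjusted p = 0.22).

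Ribosome biogenesis factors were ordered by the length of their coding sequence. Among the 36 with the shortest (192 to 1176 nt) 17 fell and none rose (median -0.51), among the 35 in the middle (1236 to 2064 nt) 3 fell (median -0.23), and among the 36 longest (2100 to 6813 nt) 2 rose and none fell (median 0.16). Spearman's rho across genes between coding length and mean log2 ratio was 0.61 (0.52 in SUM1315, 0.61 in SKBR3 and 0.54 in T47D), where genes are not independent replicates. Other genes of the same coding lengths and like expression had medians of -0.07, -0.09 and 0.03. Of 16 lists compared in this way, rho also stood apart from random lists in G2/M genes (0.66, permutation p = 2e-04, adjusted p = 0.0011), G1/S genes (0.65, permutation p = 8e-04, adjusted p = 0.0032), 5 prime TOP translation factors (0.57, permutation p = 0.0062, adjusted p = 0.019), HIF targets (-0.47, permutation p = 2e-04, adjusted p = 0.0011) and oxidative phosphorylation genes (-0.38, permutation p = 0.007, adjusted p = 0.019; -0.27 in SUM1315, 0.04 in SKBR3 and -0.69 in T47D), and it was 0.02 in ribosomal proteins (adjusted p = 0.32). These tests are two-sided and 2e-04 is the smallest p that 10000 random lists can give.

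The tables argue against a trend with coding length shared by all genes as the whole cause of this order, since 0 percent of 10000 random lists of like expression had a rho as high (random median 0.14). A trend with expression level, transcript length or GC content may still account for part of it: after its removal rho was 0.54, but in SUM1315 it was 0.38, under the bound of 0.4 set for each line. A dependence of ribosome loading on coding length within these groups is a hypothesis only, since these groups were picked out on the same libraries and RNA from whole lysates was not analysed here.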
